A study of Homo sapiens with 6 samples.

How the data were processed

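Total RNA from CL1-5, a highly invasive human lung adenocarcinoma cell line, was measured on 6 spotted cDNA arrays with 1 array per condition. The first condition was cells without macrophage-conditioned medium (CM) and without tanshinone I, a compound from the root of Salvia miltiorrhiza. The other 5 conditions were cells in CM with tanshinone I at 0, 0.01, 0.1, 1 or 10 µg/mL. Per the labels' protocols, 30 µg of RNA was labelled with digoxigenin during reverse transcription, so each array carried 1 label, and the scanned image was digitized with GenePix 5.0.

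The deposited values were linear spot intensities. Per the series' design text, the authors averaged 3 copies of each spot, rescaled the intensities between arrays with a quantile method and the GAPDH housekeeping gene, and set values under 2330 to 2330. The values fit the averaging and the floor: the lowest value was 2330 in each array, and 100% of the values above it were multiples of a 3-copy step within a tolerance of 0.01. The columns did not share 1 distribution, and which of the authors' steps left them different was not tested. The labels state that experiments were performed 3 times, but 1 column per condition was used here, and whether it averages repeats is not given in the sources used here. The authors' own grouping of profiles by self-organizing maps in Acuity 3.0, described in the design text, was not used here. No genome build is involved.

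The 1152 features carry position-like IDs in 12 prefixes of 96 features each. None of these IDs matched a gene name or accession in the gene table used here (0 of 1152), and the files do not pair them with genes. Gene names, genome positions, the fixed gene lists and cell type marker lists, and scaling to the GAPDH spot were therefore not used. The rule for naming genes left features without a gene name unnamed. The few feature IDs printed below were chosen after their values were seen: the 2 largest differences each way among features above the floor on both arrays of a comparison, all members of a deposited-scale count of 3 or fewer, and, in the closing section, 3 further members of the group that was up with CM and down at 10 µg/mL, picked as examples.

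With 1 array per condition, no comparison has a replicate check, and no p-value or standard error of a difference between conditions was made from features. An SD over features describes their scatter and is not a replicate error. Differences were taken as log2 of the deposited intensity with no pseudocount. A feature was compared between 2 arrays if it was above the floor in at least 1 of them, and it was counted when the intensities were at least 2-fold apart. Where 1 side was at the floor the fold is a lower bound. The counts of all 15 pairs of arrays were set side by side to show how far arrays lay apart. For the dose trend, a feature was counted when its value never stepped against the direction over the 5 doses, ties allowed, and differed at least 2-fold between 0 and 10 µg/mL. The count was compared with those of all 60 orders of the 5 arrays, an order and its mirror being 1, in an exact permutation test whose smallest possible p is 0.017. Reversal of the CM difference at 10 µg/mL was counted and compared with all 120 ordered choices of 3 arrays, where a choice and its mirror give the same count and both were kept. Brightness classes split the 852 features above the floor in at least 1 array into 4 equal classes by their mean log2 intensity over all 6 arrays.

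The design, the thresholds and most alternatives were set before the data were examined. The alternatives were fold thresholds of 1.5 and 3, centring each array on its median, quantile normalization, a floor raised to 4660, and features above the floor in all 6 arrays. For single results, doses were left out, a step against the direction was allowed, and other control arrays were used. Quantile normalization was planned, but its treatment of features tied at the floor was revised after seeing the data. It was first run with these features at their average rank, which opened a gap above the floor in dim arrays. The quantile counts in the text come from the revised form with 1 common floor unless average ranks are named. Scaling to a common 75th percentile, a floor of 3964 without scaling, and a split of the doses were added after seeing the data. After any scaling, 1 common floor was set at the highest scaled floor before logs were taken. This floor was 3964 after quantile normalization, 4106 after 75th percentile scaling and 2456 after median centring. The code was tested on simulated arrays of 1152 features with noise of 0.1 on the log2 scale, and it recovered 100% of 50 features lowered by 1.5 log2 units between CM and no CM and 100% of 50 features lowered by that amount along the doses. The lowered features were drawn from bright features only, and no brightness difference between arrays was simulated for these counts. The recovery therefore checks the code and does not show how many changes these floored arrays could detect. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.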

Results

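Gene expression was profiled in CL1-5 lung adenocarcinoma cells on 6 arrays of 1152 features, 1 array for each of 6 conditions. The design asks how medium conditioned by macrophages (CM) changes expression in these cells, and which features follow the concentration of tanshinone I given with that medium. Features are identified by array ID because the files do not name their genes. Of the 1152 features, 300 were at the floor of 2330 intensity units in all 6 arrays, 852 were above it in at least 1 array, and 277 were above it in all 6. The number of arrays limits the precision of every value below, and none has a replicate.

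The arrays differed in overall brightness. Features above the floor numbered 660 (57.3%) without CM, 509 (44.2%) with CM alone, 690 (59.9%) at 0.01 µg/mL tanshinone I and 679 (58.9%) at 0.1 µg/mL. They numbered 308 (26.7%) at 1 µg/mL and 368 (31.9%) at 10 µg/mL. Among the 277 features above the floor in all arrays, the median intensity was 11009 without CM, 8841 with CM alone, 9479 at 0.01 µg/mL, 11419 at 0.1 µg/mL, 4892 at 1 µg/mL and 4813 at 10 µg/mL. The highest intensities were similar, from 24073 at 0.1 µg/mL to 27395 at 1 µg/mL.

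The differences of the 1 and 10 µg/mL arrays from the CM array varied with the brightness of the features. For dim features the floor limited what could be seen. In the brightest class of 213 features the mean log2 difference from CM was -0.70 at 1 µg/mL and -0.71 at 10 µg/mL, with SDs over features of 0.64 and 0.60. In the next class it was -0.60 and -0.54, with SDs over features of 0.58 and 0.59, but 124 of its 213 features at 1 µg/mL and 75 at 10 µg/mL were at the floor, which limits how low they could read. In the dimmest class no difference could be seen, since 189 of 213 features were already at the floor in CM alone, 212 at 1 µg/mL and 205 at 10 µg/mL. Among the 20 features brightest without CM, an array outside this comparison, the median log2 difference from CM was -0.15 at 1 µg/mL and -0.19 at 10 µg/mL, and 0 and 1 of them were 2-fold lower.

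**Figure D1:**
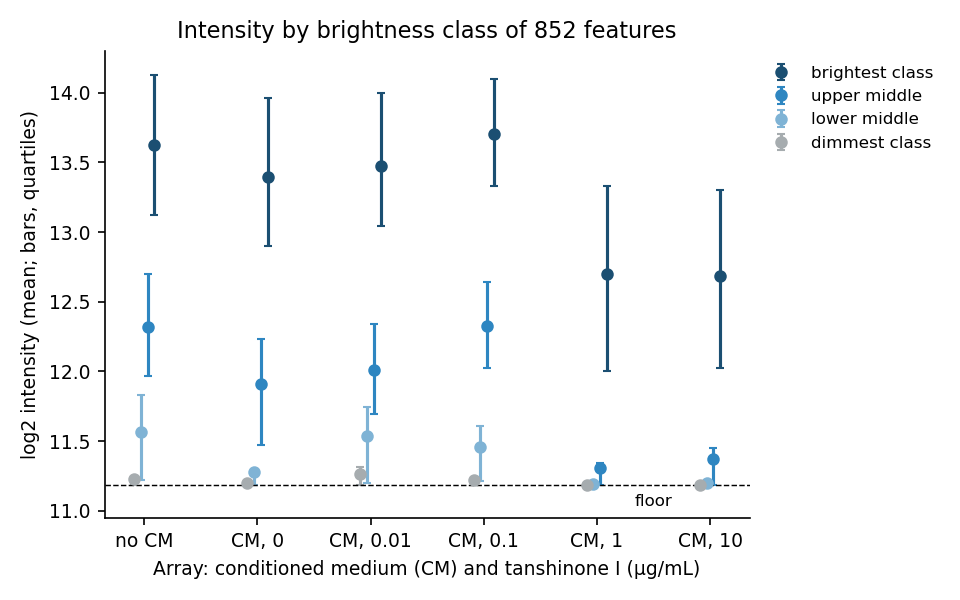
Mean log2 intensity (y axis) of 4 brightness classes, of 213 features each, on the 6 arrays (x axis). Points are means over features, bars run from the 25th to the 75th percentile of features and do not show replicate error, and the dashed line is the floor of 2330. The brightest class lay lowest at 1 and 10 µg/mL, and the dimmest class lay near the floor on all arrays.

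CM was compared with no CM to ask which features respond to the medium. Of 690 features compared, 9 were at least 2-fold higher with CM and 66 were at least 2-fold lower. Feature M1f10 was 3.25-fold higher with CM, at 9824 against 3027 intensity units, and feature M1e11 was 3.02-fold higher, at 7248 against 2398. Feature M1h09 was 3.61-fold lower, at 2680 against 9682, and feature A1f02 was 3.57-fold lower, at 2827 against 10094. Both M1f10 and M1e11 stayed high in CM with 0.01 and 0.1 µg/mL tanshinone I, where M1f10 read 9737 and 10860 and M1e11 read 6580 and 9485.

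The surplus of lower features went with a dimmer CM array. Over the 479 features above the floor on both arrays the median log2 difference was -0.31, and 355 of them (74.1%) were lower with CM. After quantile normalization, which brings the arrays to 1 distribution and so the median difference near 0 by construction, that difference was -0.02. Then 13 features were higher and 3 lower, so the direction of the surplus turned. Scaling to a common 75th percentile gave 16 higher and 2 lower, and median centring gave 16 higher and 35 lower. The median of the CM array is the floor itself, so median centring removed little of its dimness. The median log2 difference was still -0.20 after it. M1f10 and M1e11 remained higher and M1h09 and A1f02 remained lower under these scalings. After quantile normalization 1 side of each lay at the common floor, so the differences are bounds: at least 2.27-fold and 1.70-fold higher and at least 1.90-fold and 1.97-fold lower. M1f10 kept its 2-fold difference, and the bounds of the other 3 were too low to call them. With floor features at their average rank in place of the common floor, M1e11 was 2.84-fold higher and M1h09 and A1f02 were 2.51-fold and 2.50-fold lower. Of the 9 features higher as deposited, 5 were also 2-fold higher after quantile normalization and after 75th percentile scaling. Of the 66 lower features, 2 were also 2-fold lower after quantile normalization and after 75th percentile scaling. Part of this loss comes from the raised common floor, since setting the floor at 3964 without scaling left 5 features higher and 27 lower. A further 198 features were at the floor on 1 side with a bound under 2-fold and could not be placed.

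Each tanshinone I dose was compared with CM alone to ask which features respond to the compound. At 10 µg/mL, 112 of 528 compared features were at least 2-fold lower and 2 were higher. Feature M4b10 was 4.61-fold lower, at 2965 against 13665 intensity units, and feature A1e06 was 4.18-fold lower, at 2465 against 10307. Both were also lower at 1 µg/mL, by 3.13-fold and 4.24-fold. The 2 higher features were A3b01, at 7746 against 3692 (2.10-fold), and M3a02, at 9998 against the floor, which is at least 4.29-fold higher. A3b01 read 14271 at 0.01 µg/mL and 4393 at 0.1 µg/mL, so its value did not follow the dose.

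At 1 µg/mL, 112 of 523 compared features were lower and 3 were higher. The 3 were A3b01, M3a02 and M1c10, which read 4664 at 1 µg/mL and was at the floor in CM alone and at 10 µg/mL. Of the 112 lower at 1 µg/mL and the 112 lower at 10 µg/mL, 87 were shared, against 24.4 for independent lists. Both comparisons use the same CM array, so part of this excess may come from it. With different baselines for the 2 doses, taken among the 3 lower-dose CM arrays, the overlap varied. With CM as the baseline of 1 µg/mL and 0.01 µg/mL as that of 10 µg/mL, 38 features were shared against 28.9 for independent lists, and with those 2 baselines exchanged 39 against 24.6. The 4 choices that used the 0.1 µg/mL array gave 89 against 48.0, 72 against 42.8, 91 against 51.4 and 82 against 51.7. All these values for independent lists, 24.4 included, are over all compared features. They are likely too low because dim features could not be called 2-fold lower, so the size of any excess is not known. The 1 and 10 µg/mL arrays were the closest pair of the 15, with 5 of 388 compared features 2-fold apart. They also had the most features at the floor, 844 and 784, which limits this count. Of the 388, 99 were at the floor on 1 side and could not be placed. After quantile normalization that pair had 5, the 1 µg/mL array also had 5 against 0.01 µg/mL and 5 against 0.1 µg/mL, and the 0.01 and 0.1 µg/mL arrays were the closest, with 3.

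The 2 lower doses had more higher than lower features, where the 2 higher doses had more lower ones. At 0.01 µg/mL, 46 of 735 compared features were higher and 31 lower, and at 0.1 µg/mL 29 of 697 were higher and 4 lower. The 15 pairs ranged from 5 to 243 features 2-fold apart, with a median of 114. The 8 pairs with the most such features were those that set the 1 or the 10 µg/mL array against 1 of the other 4 arrays. CM differed from no CM by 75 features and from 0.01 µg/mL by 77.

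The count at the 2 higher doses depended on the floor and on the scaling. Setting the floor at 3964 without scaling left 1 feature higher and 66 lower at 10 µg/mL and 1 higher and 65 lower at 1 µg/mL. Quantile normalization, which ends at that same floor, gave 10 features higher and 8 lower at 10 µg/mL and 12 higher and 8 lower at 1 µg/mL. With floor features at their average rank it gave 21 higher and 29 lower at 10 µg/mL and 20 higher and 40 lower at 1 µg/mL. At the 2 lower doses the common-floor form gave 10 higher and 14 lower at 0.01 µg/mL and 3 higher and 6 lower at 0.1 µg/mL. All 8 features lower at 10 µg/mL after quantile normalization were among the 112, and all 8 were also lower after 75th percentile scaling. Both features higher at 10 µg/mL stayed 2-fold higher under these scalings. The 75th percentile itself was near the floor at the 2 higher doses, 2427 at 1 µg/mL and 2588 at 10 µg/mL against 4249.5 in CM alone. That scaling therefore rests on dim features. Among features above the floor on both arrays, the median log2 difference at 10 µg/mL was -0.63 as deposited and -0.02 after quantile normalization. A median near 0 follows from that method, whatever the cause of the difference. After quantile normalization M4b10 was 2.38-fold lower and A1e06 at least 2.44-fold lower, with its value at 10 µg/mL at the common floor.

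**Figure D2:**
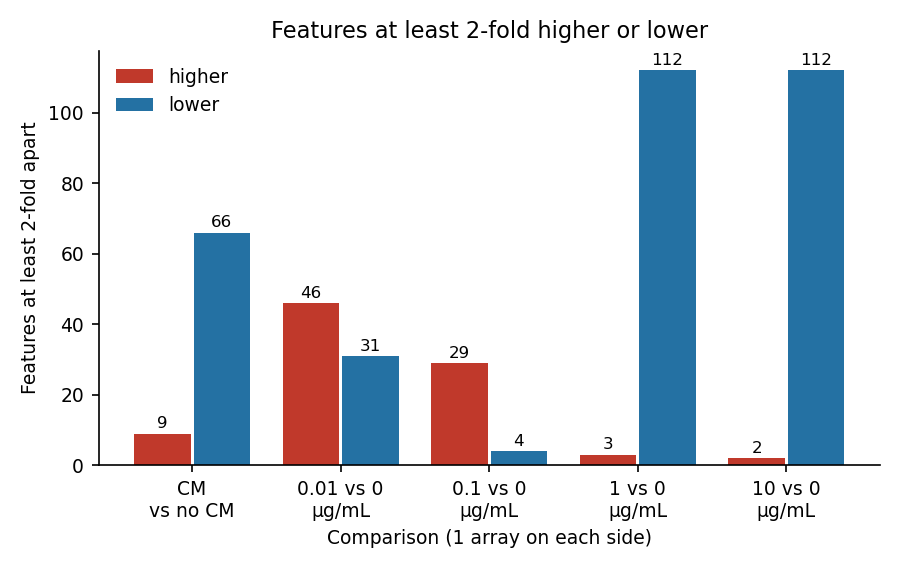
Number of features at least 2-fold higher or lower (y axis) in each of 5 comparisons (x axis), from deposited intensities with 1 array on each side and no replicate error. Lower features number 112 at 1 and at 10 µg/mL, against 31 and 4 at 0.01 and 0.1 µg/mL.

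The dose trend asks which features follow the tanshinone I concentration, as the submitters' own profile clustering did. Only 3 of the 1152 features moved in 1 direction through all 5 doses and differed 2-fold between the ends. Feature M3a02 stepped up, from the floor in CM alone to 3165 at 0.01 µg/mL, 6727 at 0.1 µg/mL, 7309 at 1 µg/mL and 9998 at 10 µg/mL. It read 3211 without CM. Features A3d12 and M7e02 stepped down. A3d12 read 21981, 19867, 19224, 13051 and 9373 over the rising doses, and M7e02 read 18047, 16864, 16612, 12405 and 6400. After quantile normalization the log2 differences between 0 and 10 µg/mL were -0.56 for A3d12 and -0.72 for M7e02. Both are under 2-fold, and 0 falling features were left.

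Of the 60 orders of the 5 arrays, 36 gave 3 or more features (exact permutation p = 0.60, two-sided over rising and falling features together). The median order gave 7.5 features and the highest gave 60. The order with 60 features was that of the arrays' mean intensity, from 0.1 µg/mL through 0.01 µg/mL, CM alone and 1 µg/mL to 10 µg/mL, which is computed from the same values. Leaving out the CM array, the 0.01 µg/mL array or the 0.1 µg/mL array raised the number of falling features from 2 to 46, 19 and 43, with exact permutation p of 0.25, 0.33 and 0.33. With 4 arrays the smallest possible p is 0.083.

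**Figure D3:**
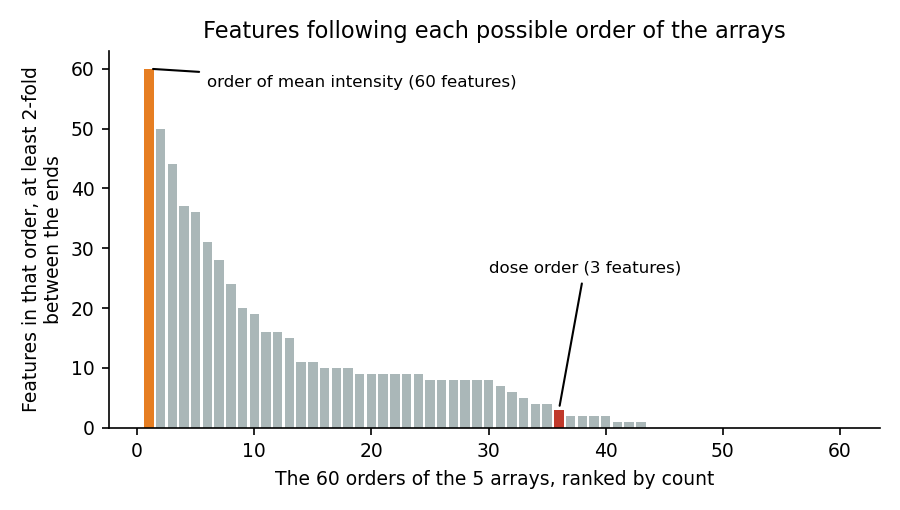
Number of features that follow each of the 60 possible orders of the 5 conditioned medium arrays and differ at least 2-fold between the ends (y axis), with orders ranked by count (x axis). The dose order gives 3 features, the order of mean intensity gives 60, and 36 orders give at least as many as the dose order.

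Reversal asks which features changed with CM and returned with 10 µg/mL tanshinone I. There were 7 features 2-fold higher with CM and 2-fold lower again at 10 µg/mL, out of the 9 higher with CM, and 0 features with the opposite pattern. Only 2 features were higher at 10 µg/mL and independent lists would share 0.21, so a 0 there was likely beforehand. M1f10 was among the 7: it read 3027 without CM, 9824 with CM and 3650 with 10 µg/mL, a 2.69-fold lower value. M1e11, also higher with CM, was 1.89-fold lower at 10 µg/mL and was not among them. Both differences share the CM array, which alone gives opposite changes, and of the 120 ordered choices of 3 arrays 62 gave 7 or more such features, with a median of 8. The 120 hold each choice together with its mirror, which has the same count, so the 62 include the mirror of the choice tested here. For the pattern with 7 features, independent lists over all compared features would share 1.94, which is likely too low because dim features could not be called. With the 0.01 µg/mL array in place of CM for the tanshinone I difference, the count was 4. The count was 2 after quantile normalization, 3 after 75th percentile scaling, 12 after median centring and 0 at 3-fold.

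**Figure D4:**
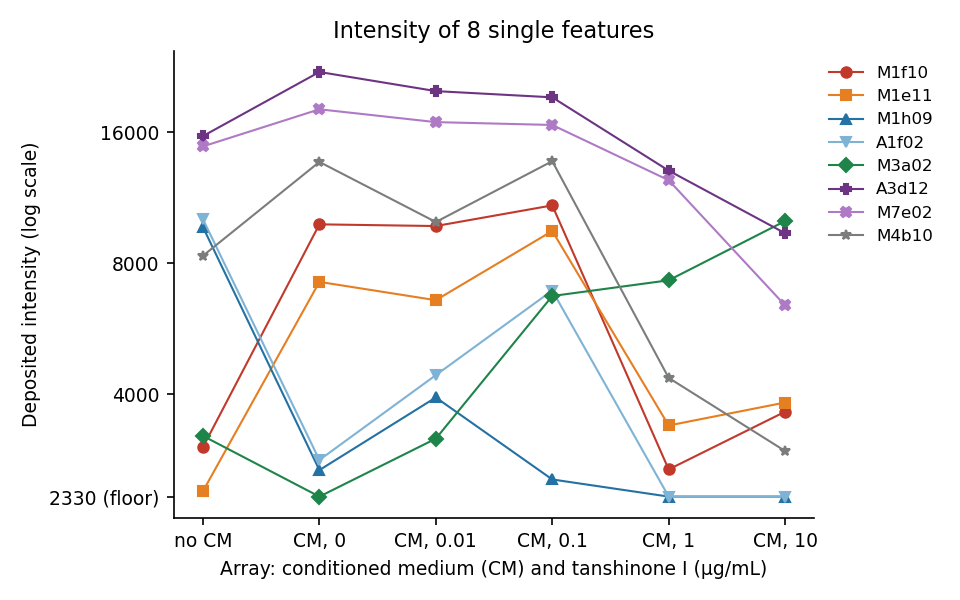
Deposited intensity (y axis, log scale) of 8 single features on the 6 arrays (x axis), 1 array per point. M1f10 and M1e11 are highest in the arrays with CM and 0 to 0.1 µg/mL tanshinone I, M1h09 and A1f02 are highest without CM, and M3a02 steps up through all 5 doses.

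The features at least 2-fold lower at 10 µg/mL were spread over the array IDs. All 12 ID prefixes held some, from 10.8% of compared features in prefixes A2 and M3 to 36.7% in prefixes A1 and M5. The prefix with the most features above the floor in any array was M7, with 94 of 96, and prefix A4 had the fewest, with 46.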

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

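Values below are numbers of features, given as higher and lower for CM against no CM and then for 0.01, 0.1, 1 and 10 µg/mL against CM. As deposited at 2-fold they were 9 and 66, 46 and 31, 29 and 4, 3 and 112, and 2 and 112. At 1.5-fold they were 34 and 189, 131 and 66, 138 and 13, 8 and 234, and 7 and 228. At 3-fold they were 3 and 3, 6 and 7, 2 and 2, 1 and 36, and 1 and 24. Both thresholds move counts by construction. With the floor raised to 4660 they were 4 and 22, 11 and 11, 10 and 3, 1 and 47, and 1 and 47. With only the 277 features above the floor on all arrays they were 6 and 28, 20 and 12, 18 and 1, 1 and 72, and 1 and 74. These 2 settings leave fewer features. Median centring gave 16 and 35, 27 and 35, 19 and 6, 3 and 112, and 2 and 112. It leaves the comparisons of 1 and 10 µg/mL with CM as they were because the median of all 3 arrays is the floor itself. Quantile normalization gave 13 and 3, 10 and 14, 3 and 6, 12 and 8, and 10 and 8, and 75th percentile scaling, added after seeing the data, gave 16 and 2, 8 and 20, 2 and 7, 19 and 15, and 9 and 14. Quantile normalization with floor values left at their average rank, which was run first and replaced after its result was seen because it opens a gap above the floor in dim arrays, gave 20 and 7, 26 and 32, 5 and 8, 20 and 40, and 21 and 29. A floor of 3964 without scaling, added after seeing the data to separate the floor from the scaling, gave 5 and 27, 14 and 19, 14 and 3, 1 and 65, and 1 and 66. The mean of 1 and 10 µg/mL against the mean of 0 and 0.01 µg/mL gave 1 and 80. Asking that both high doses lie 2-fold beyond all 3 lower doses, added after seeing the data, gave 0 and 31. Rising and falling features in dose order, 1 and 2 as deposited, were 3 and 4 at 1.5-fold, 1 and 0 at 3-fold, 8 and 23 with no minimum fold, 1 and 49 with 1 step against the direction allowed, 0 and 2 among features above the floor on all arrays, 2 and 0 after quantile normalization, 5 and 3 with average ranks, and 1 and 1 after 75th percentile scaling. Leaving out each dose in turn gave 1 to 2 rising and 2 to 46 falling features. The exact permutation p of the dose order was 0.32 to 0.78 over the settings that keep all 5 arrays, where it did not pass 0.05. With 1 dose left out it was 0.25 to 0.92, where 4 arrays cannot give a p under 0.083. The 7 features up with CM and down at 10 µg/mL became 27 at 1.5-fold, 0 at 3-fold, 4 with the raised floor, 5 among features above the floor on all arrays, 12 after median centring, 2 after quantile normalization, 5 with average ranks, 3 after 75th percentile scaling and 4 with the 0.01 µg/mL array as control. The opposite pattern had 0 features except for 2 at 1.5-fold. Over the 15 pairs, the fewest and most features 2-fold apart were 5 and 243 as deposited, 3 and 27 after quantile normalization and 2 and 154 among features above the floor on all arrays. For 10 of the single features, 7 settings gave 67 values, none of opposite direction. Of these values 17 equal the deposited one because the setting did not act on those arrays or features. The features were picked from the same data for large differences, so a kept direction was likely beforehand and is no separate support. Scaling to the GAPDH spot, the choice between probes of 1 gene and the gene lists were not run because no feature has a gene name here. No paired analysis was possible because each condition has 1 array. Signal over the floor limits these data: 784 to 844 of 1152 features were at the floor at 1 and 10 µg/mL, so a lower value there often has only a bound.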

Other observations

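Single features differed from the general course of the arrays. Feature A3b01 was higher at 10 µg/mL although that array was dim, and its log2 difference from CM was 1.07 as deposited and at least 1.61 after quantile normalization, where CM lay at the common floor. Besides M1f10, 6 features were 2-fold up with CM and 2-fold down at 10 µg/mL, and 3 of them follow. Feature M5a12 read 9842 without CM, 21825 with CM alone, 20639 at 0.01 µg/mL, 21940 at 0.1 µg/mL, 12673 at 1 µg/mL and 10252 at 10 µg/mL. Feature A1b11 read 3471, 9146, 10799, 11827, 7600 and 3612 on the same arrays. Feature A4c07 read 5085, 13830, 8591, 3811, 3349 and 4740, so it was already low at 0.1 µg/mL. These features were singled out after their values were seen.

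The 2 tests of explanations for the lower intensities and the split of the doses were chosen or revised after the results were seen, and the permutation of the dose order was planned. The arrays at 1 and 10 µg/mL had 112 features each that were 2-fold lower than CM alone, and a candidate explanation is an array-wide rescaling, in labelling, exposure or the authors' normalization. After quantile normalization with 1 common floor, 20 features at 1 µg/mL and 18 at 10 µg/mL were 2-fold apart from CM, not above the highest count of 24 among the 6 pairs of arrays under 1 µg/mL, while with floor values at their average rank they were 60 and 50 against 58. A single factor for every feature would also move the 20 features brightest without CM, whose median log2 difference at 10 µg/mL was -0.19 (range -1.17 to 0.21), unless they are saturated, which was not tested. A fall limited to some ID prefixes is argued against by the prefix's share of 0.051 of the variance of the log2 differences at 10 µg/mL, but what the prefixes stand for is not given in the sources used here, so spot position was not tested. An effect of tanshinone I on many transcripts at once stays open, since quantile normalization would remove it too and each dose has 1 array.

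Few features followed the dose order, 3 against a median of 7.5 over the 60 orders. After quantile normalization the dose order had 2 features, both rising, and 27 of 60 orders had at least as many (exact permutation p = 0.45). When the 5 arrays were split into 2 and 3 instead, 31 features separated the 2 high doses from the other 3 arrays by 2-fold, and the highest of the other 9 splits, CM alone with 0.1 µg/mL against the rest, gave 15. With 10 splits no share under 0.05 can be had. A step between 0.1 and 1 µg/mL, in place of a graded response, is a hypothesis that these arrays cannot separate from brightness.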
